A study of Rattus norvegicus with 8 samples.

How the data were processed

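Total RNA came from the cortex around the injury site in 4 rats with moderate traumatic brain injury and from the same site in 4 sham rats, 24 h after injury. Animals were perfused with 100 ml of saline at 4 °C, and samples with an RNA integrity number of at least 7 were used, per the labels. Libraries were made with a stranded total RNA kit that removes ribosomal RNA, per the labels. The submitters' processing notes name Trimmomatic 0.36, DESeq and the genome build Rnor 6.0. The aligner and the circRNA caller are not given in the sources used here. The labels describe 8 separate cortex samples, and samples were grouped as the labels give them.

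The authors deposited RPM values, which per the file headers cover 8 libraries, 1 column each, with chromosome, start, end and strand of every circRNA. Within each library all values above 0 were whole multiples, within 0.01 read, of 0.5 times the smallest one, so that the smallest listed value was taken as 2 reads. This gave a denominator of 76300000 to 77700000 reads per library, rounded. A value of 1 read cannot occur on that reading, which sets the smallest listed value at 2 reads. The main tests used the RPM values, as planned. The reads behind them were used in the limma voom alternative, for thinning and for read-based limits. They were also used to compare replicates with counting noise, for the simulated reads and for the Poisson counts. All of these rest on the smallest value being 2 reads. Listed circRNAs spanned 138 to 99986 bases, with a median of 12157. Replicates differed by more than counting noise, with a chi-square per degree of freedom of 2.87 to 3.64 between libraries of one group over circRNAs with at least 20 reads in the pair.

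circRNAs listed above 0 in at least 4 of 8 libraries were tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend) on log2(RPM + pseudocount), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The pseudocount, 0.0259 RPM, was the median over libraries of the smallest listed value, taken as 2 reads where about 1 had been foreseen. Fold changes are therefore on the log2(RPM + pseudocount) scale, which understates the change of low circRNAs. Unequal change within a locus was tested with limma diffSplice. Totals per library were compared with exact permutation tests over the 70 assignments of 8 libraries to 2 groups. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and drawn with matplotlib 3.10.9.

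The tests, the groups, the rule for named items and most alternatives were fixed before the data were examined. The rule names, per direction, up to 12 circRNAs past the threshold whose groups do not overlap, filled by smallest p up to 6, then the 8 with the highest mean. For loci it names the 5 with the most tested circRNAs, the 5 with the smallest diffSplice p, and up to 6 totals per direction. Not all of these are described with values in the text. The tests had been planned on host genes. The table names none, and the gene table at hand is for another assembly, GRCr8, so no positions were converted and no gene was assigned. Loci took the place of host genes, a choice made after seeing the data. A locus joins circRNAs of one strand that share an exact start or end, which gave 16050 loci, 9221 of them with 1 circRNA. The 26 gene lists fixed beforehand, with 1180 genes, could not be tested, since 0 of their genes are named in the table.

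The functions were tested on simulated reads for the real circRNAs, with 100 circRNAs or loci changed 2-fold and 100 changed 4-fold. For locus totals averaging at least 10 reads, 89% of 2-fold changes were recovered, and for a changed share within a locus 4 of the 98 2-fold changes that could be tested (4.08%) and 55% of 4-fold changes. The simulated spread between animals was the median of the real circRNAs averaging at least 40 reads, and was given to all circRNAs. These shares are therefore upper figures for circRNAs that vary more. They are also upper figures where fewer circRNAs or loci are called, since the adjusted threshold is then stricter. With no change simulated, 0 circRNAs were called by limma, with 4.42% at an unadjusted p under 0.05. Abundant circRNAs listed at 0 in some libraries were not simulated, so these 0 calls set no limit on false calls among such circRNAs. Alternatives covered the pseudocount, the filter, the scaling, the variance model, the replicate number and each library left out in turn.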

Results

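Circular RNAs (circRNAs) are transcripts whose ends are joined by back-splicing, so that each is recognised by the reads that cross its junction. They were profiled in total RNA from rat cerebral cortex, in 4 animals with moderate traumatic brain injury (mTBI) and 4 sham animals, 1 library each. The tissue was the cortex around the injury, or the same site in sham animals, taken 24 h after injury. The deposited table held 51995 circRNAs with their junction positions in RPM, reads scaled to the library's total, and no gene names, so circRNAs are named here by position on Rnor_6.0. Summed over circRNAs, the 8 libraries held 4966 to 5874 RPM, or 384910 to 452692 junction reads per library if the smallest listed value is taken as 2 reads. Each library listed 21508 to 23713 circRNAs above 0. Of all circRNAs, 9082 were listed in all 8 libraries and made up 85.8% of the RPM, while 20544 were listed in 1 library only. On that reading, which the steps between values allow but do not prove and on which all read numbers here rest, a circRNA listed at 0 may have had 1 read or none, or may not have been called.

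The first comparison asked which circRNAs differed in abundance between injured and sham cortex. Of 20174 circRNAs tested, 5 passed an adjusted p of 0.05, 2 higher and 3 lower after mTBI (limma). The most abundant of them, on the plus strand of chromosome 16 from 26755422 to 26780008, stood at 6.37, 7.34, 9.03 and 10.1 RPM in the mTBI libraries. In sham it was listed at 0 in 3 libraries and at 6.99 RPM in sham replicate 3, so the groups overlapped (limma adjusted p = 0.00220). That p depends on variance taken from other circRNAs, as described below. A circRNA with the same start, ending at 26767549, stood at 1.27 to 1.34 RPM in sham and 1.25 to 1.86 RPM in mTBI. The second with a higher level, on the plus strand of chromosome 1 from 278661823 to 278749829, was listed at 0 in all 4 sham libraries and at 0.0387, 0.592, 0.482 and 0.584 RPM in mTBI (adjusted p = 0.00463).

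Among the 3 that were lower after mTBI, the circRNA on the plus strand of chromosome 15 from 61665894 to 61683055 was listed in every library. It fell from 0.629 ± 0.155 RPM in sham to 0.191 ± 0.122 RPM in mTBI (SD, n = 4 each), with a log2 change of -1.71 (SE 0.30, limma adjusted p = 0.0149), and all 4 mTBI values lay below all 4 sham values. The circRNA on the plus strand of chromosome 6 from 112684486 to 112689839 stood at 0.168, 0.144, 0.311 and 0.258 RPM in sham and was listed at 0 in all 4 mTBI libraries (adjusted p = 0.00463). The circRNA on the minus strand of chromosome 1 from 119464809 to 119545970 stood at 2.73, 0.695, 2.20 and 3.21 RPM in sham, at 2.62 RPM in mTBI replicate 1 and at 0 in the other mTBI libraries (adjusted p = 0.0149). Fold changes here are on the scale of log2(RPM + 0.0259), and none is given against libraries listed at 0.

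**Figure D1:**
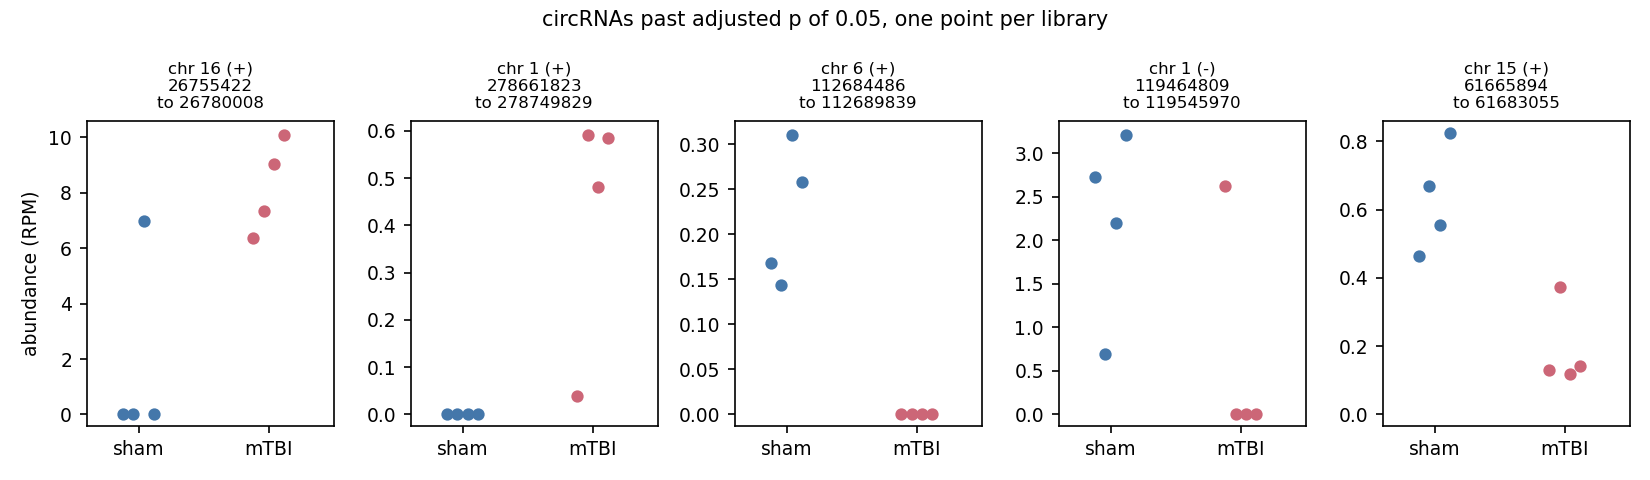
Abundance in RPM (vertical axes, a separate scale for each panel) of the 5 circRNAs with an adjusted p under 0.05, with one point per library and sham left of mTBI. In 4 of the panels at least 3 libraries of one group are listed at 0, and the chromosome 15 circRNA at the right is above 0 in all 8 libraries.

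The chromosome 16 circRNA passed without each library in turn, but not without the variance trend (limma adjusted p = 0.371) or with robust variance shrinkage (0.917), at the same log2 change. Its limma adjusted p ran from 4.48e-171, with no filter, to 0.917 over all alternatives. At the same log2 change, 6.27, the SE was 0.913 in the planned fit and 0.222 with no filter. The p therefore depends on variance that limma takes from the other circRNAs, and does not by itself measure the spread between animals. The minus-strand circRNA on chromosome 1 did not pass without the trend (limma adjusted p = 0.644) or with robust shrinkage (0.973) either. Only the chromosome 6 circRNA of the 5 passed without the trend (0.0230), and 3 of the 5 passed with robust shrinkage. The chromosome 15 circRNA did not pass without sham replicate 2 (limma adjusted p = 0.0809) or 4 (0.105), or without mTBI replicate 1 (0.182), 3 (0.137) or 4 (0.0849). The minus-strand circRNA on chromosome 1 was lost without sham replicate 1 (0.119) or 4 (0.0797), or without mTBI replicate 2 (0.319), 3 (0.160) or 4 (0.219). The chromosome 6 circRNA without any sham library, and the plus-strand chromosome 1 circRNA without any mTBI library, were listed in only 3 libraries and dropped below the minimum of 4 for testing. With a mean of at least 10 reads as the only filter, 0 of 6150 circRNAs passed (limma, 295 at an unadjusted p under 0.05), and limma voom on reads, over the 20174, called 3. These were the chromosome 16 and chromosome 6 circRNAs above and, chosen after its values were seen, a plus-strand circRNA on chromosome 3 from 104816866 to 104818862. It stood at 6.59 ± 0.902 RPM in sham and 4.36 ± 0.298 RPM in mTBI (SD, n = 4 each, limma voom log2 change -0.59, adjusted p = 0.0401), and did not pass the planned test (limma adjusted p = 0.221).

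Across all circRNAs tested, 944 had an unadjusted p under 0.05, against 1009 from chance alone. The 4 sham and 4 mTBI values did not overlap for 566 circRNAs (281 higher and 285 lower after mTBI), or 2.81%, where chance gives 2.86%. A log2 change smaller than 0.5 in either direction was seen for 70.1% of the 20174 circRNAs tested, for 86.5% of the 6139 of them averaging at least 10 reads and for 95.7% of the 1808 averaging at least 40 reads. Of all tested, 1093 had a log2 change of 1 or more in either direction. On simulated reads, the same test recovered 83% of 2-fold changes in circRNAs averaging at least 10 reads, and 31% over all circRNAs tested. Every simulated circRNA had the median spread of circRNAs averaging at least 40 reads, so many real ones vary more. With 100 circRNAs changed 2-fold and 100 changed 4-fold, 193 and 112 were called in these runs. Only 5 were called here, which makes the adjusted threshold stricter, so both shares are upper figures for the real data.

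Several circRNAs with small unadjusted p did not pass the threshold. On the plus strand of chromosome 15, the circRNA from 61667133 to 61683055, which shares its end with the one that fell, stood at 0.207 to 0.284 RPM in sham and at 0, 0.129, 0.0261 and 0 RPM in mTBI (adjusted p = 0.0847). On the minus strand of chromosome 7, the circRNA from 57341120 to 57356339 stood at 1.43 ± 0.0839 RPM in sham and 0.792 ± 0.190 RPM in mTBI (SD, n = 4 each, limma adjusted p = 0.163). On the plus strand of chromosome 6, the circRNA from 30550488 to 30589369 stood at 2.75 ± 1.40 RPM in sham and 5.24 ± 1.24 RPM in mTBI (SD, n = 4 each, limma adjusted p = 0.157). The minus-strand circRNA on chromosome 13 from 83256698 to 83257043 stood at 1.75 ± 1.25 RPM in sham and 0.470 ± 0.261 RPM in mTBI (limma adjusted p = 0.167). On chromosome 1, the minus-strand circRNA from 221185801 to 221186464 stood at 0.349 ± 0.324 and 0.931 ± 0.324 RPM (limma adjusted p = 0.110). The minus-strand circRNA on chromosome 2 from 23042186 to 23044366 was listed at 0 in sham replicates 1, 2 and 4 and at 0.336 RPM in sham replicate 3, against 0.248 to 0.516 RPM in mTBI (adjusted p = 0.0553). On chromosome 12, the minus-strand circRNA from 39429 to 108383 was listed at 0 in all 4 sham libraries and at 0.0900 to 0.298 RPM in mTBI (adjusted p = 0.110).

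None of the most abundant circRNAs of the cortex passed the test. The 8 with the highest mean ranged from 24.7 to 57.7 RPM, with log2 changes from -0.16 to 0.12 and a smallest adjusted p of 0.973 (limma). The highest, on the plus strand of chromosome 9 from 94463647 to 94481167, stood at 60.0 ± 5.51 RPM in sham and 55.3 ± 4.16 RPM in mTBI (SD, n = 4 each). The plus-strand circRNA on chromosome 2 from 20507150 to 20531444 stood at 50.5 ± 1.39 and 52.6 ± 2.98 RPM, and that on chromosome 3 from 81127393 to 81143240 at 46.5 ± 3.30 and 45.5 ± 4.95 RPM. On chromosome 7, the circRNA from 30727478 to 30735182 on the plus strand stood at 38.1 ± 0.763 and 37.6 ± 2.62 RPM, and the short one from 52745151 to 52745558 on the minus strand at 37.2 ± 2.07 and 35.9 ± 1.98 RPM. The circRNA with the widest spread of the 8, on the plus strand of chromosome 2 from 22950023 to 22964734, ranged from 18.6 to 51.9 RPM within the mTBI group (33.4 ± 7.34 RPM in sham, 38.7 ± 15.8 RPM in mTBI). The remaining 2 were the minus-strand circRNAs on chromosome 19 from 25886356 to 25886887 (28.1 ± 1.05 and 25.1 ± 1.65 RPM) and on chromosome 2 from 177947848 to 177973555 (24.97 ± 3.52 and 24.3 ± 4.36 RPM). For the chromosome 19 circRNA the difference was larger than either SD (limma adjusted p = 0.973).

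The next comparison summed the circRNAs of each locus, a set of same-strand circRNAs joined by shared start or end positions, in place of host genes. Of 7776 loci tested, 1 passed, the plus-strand locus on chromosome 16 from 26755234 to 26843826. Its total stood at 2.12, 1.69, 8.48 and 1.47 RPM in sham and at 8.04, 8.81, 10.7 and 12.2 RPM in mTBI (log2 change 1.91, SE 0.31, limma adjusted p = 0.0135). Without the circRNA that had itself passed, the rest of the locus stood at 1.69 ± 0.302 RPM in sham and 1.72 ± 0.255 RPM in mTBI (SD, n = 4 each). The locus did not pass without sham replicate 1 (limma adjusted p = 0.129), 2 (0.102) or 4 (0.0673), or without mTBI replicate 2 (0.0693) or 4 (0.215).

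**Figure D2:**
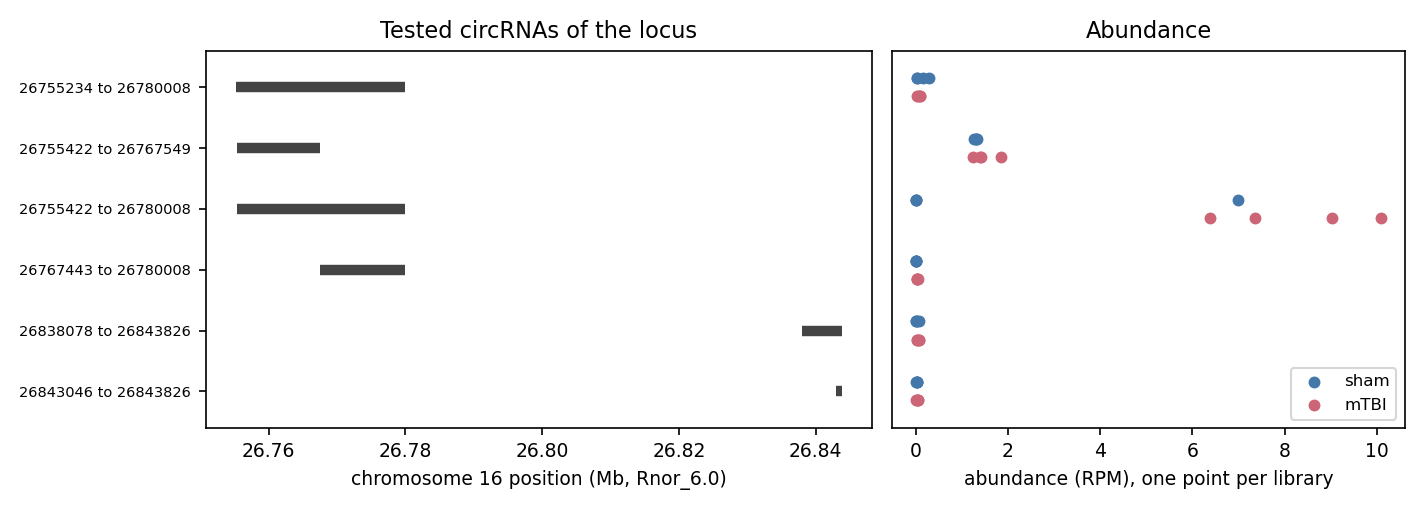
Left, the tested circRNAs of the plus-strand locus on chromosome 16 (horizontal axis in Mb, Rnor_6.0), each bar running from start to end. Right, their abundance in RPM, one point per library, with sham above and mTBI below on each line. The circRNA from 26755422 to 26780008 is at 6.37 to 10.1 RPM in mTBI and in a single sham library at 6.99 RPM.

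No other locus total passed. The plus-strand locus on chromosome 11 from 31943121 to 31996846 stood at 0.648 ± 0.0484 RPM in sham and 1.19 ± 0.103 RPM in mTBI, with no overlap between groups (limma adjusted p = 0.169). The plus-strand locus on chromosome 6 from 30546767 to 30589384 stood at 3.14 ± 1.55 and 6.16 ± 1.43 RPM (limma adjusted p = 0.169). On chromosome 7, the minus-strand locus from 57294883 to 57434518, with 13 tested circRNAs, stood at 4.03 ± 0.167 RPM in sham and 2.84 ± 0.267 RPM in mTBI (limma adjusted p = 0.608). The minus-strand locus on chromosome 13 from 83230139 to 83257043 stood at 2.49 ± 1.26 and 1.002 ± 0.715 RPM (limma adjusted p = 0.373). The loci with the most tested circRNAs held 37 to 57 each. Among them, the minus-strand locus on chromosome 9 from 28442925 to 28732920 stood at 27.0 ± 1.13 RPM in sham and 24.0 ± 1.07 RPM in mTBI (limma adjusted p = 0.951). The plus-strand locus on chromosome 19 from 34207716 to 34372833 stood at 16.6 ± 0.673 and 18.4 ± 1.36 RPM (limma adjusted p = 0.951), and that on chromosome 7 from 78122159 to 78574310 at 22.6 ± 0.0117 and 21.3 ± 1.87 RPM (limma adjusted p = 0.979).

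Whether the circRNAs of one locus changed unequally was tested in 3289 loci with at least 2 tested circRNAs, and 3 passed (limma diffSplice). In the plus-strand locus on chromosome 6 from 112603538 to 112746503, the circRNA from 112684486 to 112689839 was the one listed at 0 in all mTBI libraries, while that from 112603538 to 112609544 stood at 0.0262 to 0.181 RPM in sham and 0.0774 to 0.287 RPM in mTBI (adjusted p = 0.0109). In the plus-strand locus on chromosome 15 from 61664226 to 61683394 (diffSplice adjusted p = 0.0211), the 2 circRNAs described above that end at 61683055 were lower in mTBI. Not all circRNAs with that end fell alike. The one from 61664226 stood at 1.13 ± 0.1785 RPM in sham and 0.929 ± 0.167 RPM in mTBI (SD, n = 4 each). The one from 61678464 was listed at 0.155 RPM in sham replicate 1, at 0 in the other sham libraries and at 0.0391 to 0.0649 RPM in mTBI. The circRNA from 61665894 to 61669301 stood at 0.0388 to 0.0647 RPM in sham and 0.0651 to 0.195 RPM in mTBI. The chromosome 16 locus also passed (adjusted p = 0.0211).

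Each of these 3 loci failed the threshold when some single library was left out. The chromosome 6 locus did not pass without mTBI replicate 3 (diffSplice adjusted p = 0.110) or 4 (0.0936), nor without any 1 sham library, where its changed circRNA was no longer tested. The chromosome 15 locus passed only without sham replicate 1 (0.000131) or mTBI replicate 2 (0.00207), and the chromosome 16 locus only without sham replicate 3 (2.61e-12). Their adjusted p without each of the other libraries was 0.163 to 0.408 for chromosome 15 and 0.233 to 0.408 for chromosome 16.

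The overall abundance and number of circRNAs were compared as well. Summed abundance was 5427 ± 199 RPM in sham and 5345 ± 439 RPM in mTBI (SD, n = 4 each), a difference of -81.3 RPM (exact permutation test, two-sided, p = 0.743). Sham libraries listed 22609 ± 744 circRNAs and mTBI libraries 22454 ± 900 (SD, n = 4 each), a difference of -154 (exact permutation test, two-sided, p = 0.771). Both differences changed sign without mTBI replicate 1 (to 45.2 RPM and 77.2 circRNAs) and without mTBI replicate 2 (to 33.2 RPM and 46.9 circRNAs). The smallest p that this test can give with 4 animals per group is 0.0286.

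**Figure D3:**
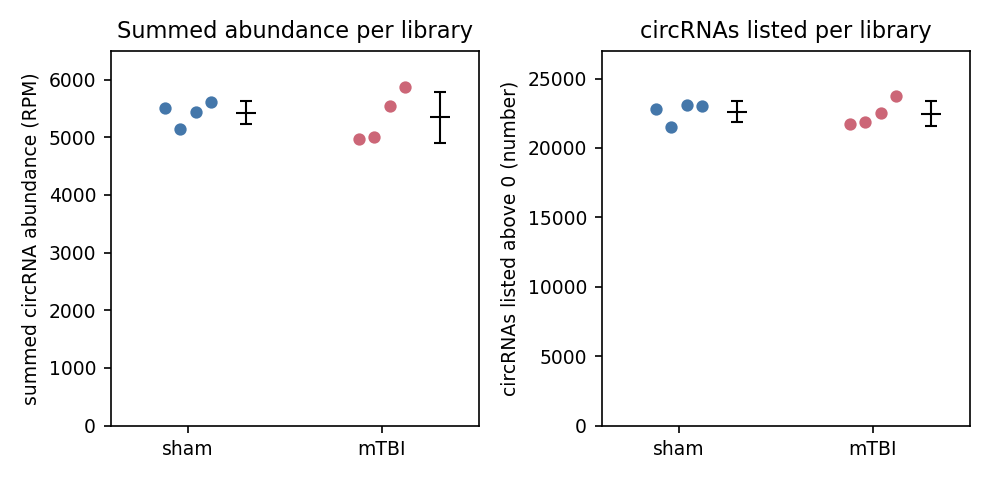
Summed circRNA abundance in RPM (left) and number of circRNAs listed above 0 (right) for each library, with sham left of mTBI in each panel; bars give the mean and SD of 4 libraries. The mTBI libraries span 4966 to 5874 RPM and the sham libraries 5148 to 5610 RPM.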

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

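In 140 groups of 4 libraries, covering the library totals, the named circRNAs and loci and the chromosome and span shares, 16 had 1 library far from the other 3. The gap to the nearest library, as a share of the group's range, was above Dixon's 95% critical value there. For independent, normally distributed values chance flags about 1 group in 20, or 7 of 140. That figure is only a guide here. Several of these groups are the same circRNA counted again in its locus. A group with a single library above 0 always gives a ratio of 1.

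In the sham group, replicate 2 listed 21508 circRNAs against 22806 to 23069 in the others (ratio 0.832). The chromosome 16 circRNA from 26755422 to 26780008 was listed at 6.99 RPM in sham replicate 3 and at 0 in the others (ratio 1), and its locus at 8.48 RPM against 1.47 to 2.12 RPM (ratio 0.907). The circRNA and locus on chromosome 2 from 23042186 to 23044366 were listed at 0.336 RPM in sham replicate 3 only (ratio 1 for both). The abundant chromosome 7 circRNA from 30727478 to 30735182 stood at 39.3 RPM in sham replicate 4 against 37.6 to 37.8 RPM (ratio 0.839). The chromosome 1 locus from 221183333 to 221189353 stood at 1.495 RPM in sham replicate 4 against 0.118 to 0.349 RPM (ratio 0.832). The chromosome 14 locus from 13211702 to 13236896 was listed at 0.0655 RPM in sham replicate 2 and at 0 in the others (ratio 1). The chromosome 6 locus from 112603538 to 112746503 stood at 0.236 RPM in sham replicate 2 against 0.569 to 0.621 RPM (ratio 0.864).

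In the mTBI group, the chromosome 12 circRNA from 39429 to 108383 stood at 0.298 RPM in replicate 4 against 0.0900 to 0.116 RPM (ratio 0.875). The chromosome 15 circRNA from 61665894 to 61683055 stood at 0.373 RPM in mTBI replicate 2 against 0.117 to 0.143 RPM (ratio 0.900). The chromosome 1 circRNA from 119464809 to 119545970 was listed at 2.62 RPM in mTBI replicate 1 and at 0 in the others (ratio 1), and its locus at 3.08 RPM against 0.0908 to 0.463 RPM (ratio 0.876). The chromosome 13 circRNA from 83256698 to 83257043 stood at 0.860 RPM in mTBI replicate 3 against 0.310 to 0.373 RPM (ratio 0.885), and its locus at 2.07 RPM against 0.579 to 0.722 RPM (ratio 0.904). The chromosome 7 locus from 43421374 to 43428623 was listed at 0.0257 RPM in mTBI replicate 2 and at 0 in the others (ratio 1).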

How the results depend on the processing

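The count of changed circRNAs, 5 in the test as planned, was 4 with 0.5 times the pseudocount and 10 with 4 times it, 55 with no filter, 0 with the stricter filter (a mean of 10 reads), 9 with libraries centred on their median, 1 without the variance trend and 3 with limma voom. Robust variance shrinkage gave 23, with 3 of the 5 among them, and a filter at a mean of 40 reads gave 0; both, and loci joined by overlap, were chosen after seeing the data. Leaving out each library in turn gave 2 to 9. Locus totals gave 1 as planned, 20 with no filter, 0 with the stricter filter, without the trend, with robust shrinkage, with the 40-read filter or with loci joined by overlap, and 0 to 2 with a library left out. Unequal change gave 3 as planned, 1 with 0.5 times the pseudocount, 4 with 4 times it, 4 with no filter, 4 with loci joined by overlap, 0 with the stricter filter, 1 with the 40-read filter and 0 to 2 with a library left out. The fourth was the minus-strand locus on chromosome 1 from 119464809 to 119565553 with 4 times the pseudocount and with no filter, and that on chromosome 15 from 84396740 to 84605901 with overlap. The 1 with the 40-read filter was none of the 3 but the minus-strand locus on chromosome 9 from 119723072 to 119807029; the last 2 loci were chosen after their values were seen. The variance trend does not enter that test. The limma counts at an unadjusted p under 0.05 beside these zeros were 295 and 80 of circRNAs, and 201, 400, 414, 92 and 321 of loci in the order given, and 57 for unequal change. The robust fit and the fit without a trend change the variance only; the cause of the other shifts was not tested.

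With the replicate number as a block, 0 circRNAs (889 at an unadjusted p under 0.05, limma), 0 loci (390) and 1 locus with unequal change were called. No shared effect of the number was seen. Residuals of same-numbered libraries correlated at 0.00873, -0.0214, -0.0173 and -0.0149, where all pairs of a sham and an mTBI library ran from -0.0467 to 0.0677. Of the sham libraries, 0 of 4 correlated best with its own number. Correlations this close to 0 throughout cannot exclude that animals were paired.

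Summed abundance differed by -258 to 45.2 RPM, and listed circRNAs by -574 to 77.2, with a library left out. Among abundant circRNAs, all far from the threshold, the log2 change crossed 0 with a library left out for those on chromosome 3 from 81127393 (-0.0983 to 0.0136), chromosome 7 from 30727478 (-0.0577 to 0.0155), chromosome 2 from 22950023 (-0.0552 to 0.439) and chromosome 2 from 177947848 (-0.145 to 0.0393). So did the loci on chromosome 7 from 114445792 (-0.132 to 0.0311, and 0.00637 after centring) and on chromosome 4 from 64389860 (-0.102 to 0.0259, and 0.0167 after centring). For named circRNAs, loci and chromosome shares, 613 values under the alternatives kept their direction and side of the threshold, 57 kept the direction but no longer passed, 36 passed only under the alternative and 12 reversed. In these counts the chromosome shares were judged on the unadjusted p of the exact permutation test, and none of them passed after adjustment. The planned count tests edgeR and DESeq2 and all gene list tests were not run, and merging equal positions on both strands had 0 circRNAs to merge.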

Other observations

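The share of circRNA abundance from each of the 22 chromosomes and from 5 classes of span was compared after seeing the data. For chromosome 16 this was also done without 1 circRNA. The tests of counting noise, of junction position, of span among circRNAs listed at 0 and of other splits were also run after seeing the data. Chromosome X gave 1.93% ± 0.0481 of the RPM in sham and 1.78% ± 0.0494 in mTBI (SD, n = 4 each), lower in 4 of 4 mTBI libraries (exact permutation test, p = 0.0286). Chromosome 7 gave 6.53% ± 0.0771 and 6.36% ± 0.0302, also lower in 4 of 4, and chromosome 16 gave 2.75% ± 0.0405 and 2.87% ± 0.0526, higher in 4 of 4 (exact permutation test, p = 0.0286 each). Without the chromosome 16 circRNA that passed the group test, the chromosome 16 shares were 2.71% ± 0.0266 and 2.72% ± 0.0647 (SD, n = 4 each, exact permutation test, p = 0.914), with 1 of 4 mTBI libraries above all sham libraries. None of the 27 shares passed after adjustment (smallest adjusted p = 0.257), and 3 stood at the smallest p that the test allows where chance gives 0.771. Spans of 1001 to 10000 bases gave 36.1% ± 0.255 of the RPM in sham and 36.2% ± 0.0535 in mTBI, and spans of 10001 to 50000 bases 45.2% ± 0.228 and 45.0% ± 0.215 (SD, n = 4 each).

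Some well-measured circRNAs were listed at 0 in part of the libraries of both groups. Of 1883 circRNAs listed in at least 4 libraries and averaging at least 0.5 RPM where listed, 34 were listed at 0 somewhere, with 33 such listings in sham and 33 in mTBI. One of them, chosen after its values were seen, runs on the plus strand of chromosome 4 from 58714647 to 58802600. It was listed at 0 in sham replicates 1 and 2 and at 4.42 to 5.67 RPM in the other libraries, while circRNAs with the same start ending at 58725647 and 58739890 stood at 10.3 to 12.9 and 3.65 to 4.48 RPM in all 8. The chromosome 16 circRNA and the minus-strand chromosome 1 circRNA that passed the group test are both among the 34.

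Counting noise does not account for these listings, since Poisson counts at each circRNA's own level would give 2.62e-13 of them against 66 seen. A junction called a few bases away does not either, since 0% of the listings had a circRNA within 50 bases at both ends at a comparable level in the same library. An inherited variant carried in 0, 1 or 2 copies may contribute. It would spread the listed values, and their median coefficient of variation was 0.248 against 0.194 in matched circRNAs, a difference of 0.0536 (95% bootstrap interval -0.0103 to 0.177). That interval allows both no extra spread and the extra spread set beforehand as the mark of such a variant. A calling step that drops some junctions in some libraries stays open beside it. Spans over 50000 or up to 500 bases made up 12 of the 34 circRNAs listed at 0 somewhere. Of circRNAs with such spans, 5.53% of 217 were listed at 0 somewhere, against 1.32% of 1666 others (Fisher's exact test, p = 0.00022). Some of the 34 share a start or an end, while this test and the bootstrap treat circRNAs as independent. The p and the interval are therefore only a guide. Why spans over 50000 or up to 500 bases were listed at 0 more often was not tested.

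The lower chromosome X share may rest in part on a few abundant circRNAs. Without the 10 most abundant X circRNAs, 3 of 4 mTBI libraries stayed below all sham libraries. An overlap of the groups was the result predicted for a few genes taking most of the counts. The overlap was narrow, with 1.235% in mTBI replicate 3 against 1.231% in sham replicate 3. The 10 did not hold most of the X share, which was 1.93% in sham with them. Without them the shares were 1.27% ± 0.0303 in sham and 1.19% ± 0.0374 in mTBI (SD, n = 4 each, exact permutation test, p = 0.0571). The difference was -0.154 percentage points with them and -0.0864 without, so a part of it remained. Leaving out circRNAs also lowers the X share of both groups, so a smaller difference does not show that the 10 carried it. The circRNA on the minus strand of X from 82845576 to 82846306, chosen after its values were seen, stood at 2.80 and 1.89 RPM in mTBI replicates 1 and 3, at 6.599 and 7.46 RPM in mTBI replicates 2 and 4, and at 6.50 to 8.96 RPM in sham. Another with the same end, from 82845848, stood at 0.942 and 0.808 RPM in mTBI replicates 1 and 3. It was at 3.37 and 3.32 RPM in mTBI replicates 2 and 4, and at 2.47 to 3.25 RPM in sham. The most abundant on X, from 63177769 to 63195572, stood at 11.8 ± 0.592 RPM in sham and 11.3 ± 1.42 RPM in mTBI (SD, n = 4 each). Chance among 27 shares also stays open.

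Chance could not be excluded for any of the group counts. Among the 35 ways to split the 8 libraries into 4 and 4, 8 called at least as many circRNAs as the 5 between sham and mTBI, and the highest of the others called 14. For locus totals, 15 of 35 splits called at least 1, and the highest other called 4. For unequal change within a locus, 4 of 35 splits called at least 3, and the highest other called 4. Library correlations were 0.790 to 0.807 between groups, 0.792 to 0.804 within sham and 0.796 to 0.805 within mTBI.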
